A study of Mus musculus with 31 samples.

How the data were processed

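Hearts of Balb/c mice aged 8 to 12 weeks were studied in the steady state (SS) or after myocardial infarction (MI), made by permanent ligation of the left anterior descending coronary artery, per the labels' protocols. Hearts were digested with Liberase and DNase, and 4 cell populations were sorted by FACS: cDC1, cDC2, CD11c-positive monocyte-derived cells (called moDCs in the labels) and CD11c-negative monocyte-derived cells (called macrophages). The sorting antibodies, the time after ligation and the sex of the mice are not given in the sources used here. The 31 libraries form 8 groups, with 4 libraries in each group except MI cDC2, which has 3. The series' design text speaks of independent replicates but does not say whether each came from a separate animal or from pooled hearts, so p-values here measure the spread between samples. Any difference in preparation between all SS and all MI hearts cannot be told apart from the effect of MI.

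Per the labels' protocols, 4 ng of total RNA per sample was amplified with SMART-Seq v4, the cDNA was sheared and made into libraries, and pooled libraries were read as 75 nt single reads on a NextSeq500. Per the submitters' processing notes, the tools were FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.1.0 and SAMtools 0.1.18 with the mm10 genome. The counting tool, the annotation and the use of strand are not given in the sources used here. The deposited values are whole-number read counts for 24421 gene symbols per sample, not normalised, with 5 further entries for reads assigned to no gene. These entries stayed out of library sizes and tests. Reads in no annotated feature came to 6.42% to 16.9% and ambiguous reads to 0.857% to 1.21% of all counted entries per library. Genes that share reads with near-identical copies, such as Hspa1a and Hspa1b, Lyz1 and Lyz2, the Cd209 family, the Ifit family and H2 genes (Balb/c alleles against a reference of another strain), are uncertain to the extent that counting could split or lose their reads.

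Reads assigned to genes numbered 9148624 to 16531349 per library. CPM values (counts scaled to equal library totals) were computed in edgeR with TMM factors. With 0 counts in a group, a fold is given as at least the value against 3 counts over the group. With 1 to 3 counts, the ratio of summed counts per read is given with its exact 95% interval. Reads amplified by PCR without molecular identifiers are not independent molecules, so such floors and intervals cover counting error only. Gene positions are from GENCODE M21 on GRCm38 (mm10), matched by symbol.

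Tests ran in R 4.3.3. The main test was edgeR 4.0.16's quasi-likelihood test (robust) on the counts, in one model with a mean for each of the 8 groups over all 31 samples, after filterByExpr by group (minimum count 10), which left 13039 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, and adjusted p under 0.05 counted as changed. The comparisons were MI against SS in each cell type, neighbouring cell types within each state, the difference of the MI effect between neighbouring cell types, and an F test of an MI effect differing among the 4 cell types. The common dispersion was 0.116. In every group the counts of the same gene varied more between replicates than counting alone gives (chi-square per degree of freedom at least 10.83).

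Gene lists of 20 biological programmes were tested for MI against SS with camera in limma 3.58.1, on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 80 list tests. Of 36 calls, 4 held when the correlation was estimated from the data: resident cardiac macrophage genes in moDCs, cDC1 and cDC2, and cDC2 identity genes in cDC1. Lists of 11 other cell types were summed as CPM per library and compared by two-sided exact permutation tests, adjusted over 44 tests. Such a test cannot give a p under 0.0286 for 4 against 4 libraries or 0.0571 for 4 against 3. Of 519 list symbols, 514 were found, 2 of them under an older symbol (Sepp1 for Selenop and Amica1 for Jaml).

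Named genes were chosen by rule. For MI against SS these are the 8 largest rises and 8 largest falls among changed genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. For neighbouring cell types in SS and for differences of MI effects, 5 in each direction were taken by the same size rule, the latter without the overlap condition. Up to 3 changed members per list with the smallest adjusted p were added. Predicted or unnamed genes, ribosomal and histone pseudogenes, immunoglobulin and T cell receptor segments, Y-linked genes and Xist were left out. Design, lists, naming rule, alternatives and splits of the samples were fixed before the data were examined. After the analysis, 2 genes that the rule chose were left out of the named genes, and not every named gene is printed.

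Libraries with the same number may come from the same preparation, which the labels do not say. Numbers were taken as pairs where every correlation of same-numbered libraries' deviations from their group means was over 0.1. This held in SS for macrophages with moDCs (0.119 to 0.203) and with cDC2 (0.109 to 0.160), the latter compared only by overlaps and the F test, from the data and not the design. In SS, numbers 1 and 4 had 11.6% to 16.9% of reads in no feature and numbers 2 and 3 had 6.42% to 9.26%, which was treated as a preparation batch. All MI libraries lay at 6.85% to 10.9%, so MI offers no such split, and each MI against SS comparison was repeated with either SS pair alone.

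Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter beyond a nonzero total, a filter of 10 mean CPM in a group, limma-voom with quality weights, a replicate block, only the samples compared, and leaving out each replicate. Added after the data were seen were the SS pairs alone, leaving out the 3 deepest libraries, and covariates for mural and endothelial CPM or for the no-feature share. The tests were run on simulated counts with known changes. For MI against SS edgeR found 64% to 71% of genes changed 4-fold and 31% to 53% of those changed 2-fold in 12747 genes, with 1.92% to 6.15% false calls. Cell types gave 70.4% to 74.1% and 39% to 48.0% in 12710 genes. Differences of MI effects gave 60% to 61.7% and 23.5% to 25.8% in 12747 genes. In simulation camera called each raised list and 0 others (other sample splits: median 15).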

Results

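RNA-seq read counts were measured in 31 libraries of dendritic cells and macrophages sorted from mouse hearts in the steady state or after MI. The series' title puts the question whether infarction activates dendritic cells, conventional (cDC1 and cDC2) or monocyte-derived, with CD11c-negative macrophages beside them. Each group had 4 libraries, and MI cDC2 had 3. Library totals ran from 9148624 to 16531349 reads in genes. The 3 deepest were SS cDC1 replicate 1 (16531349), SS moDC replicate 2 (16135415) and MI macrophage replicate 4 (15671670). Values are mean CPM ± SD, and n = 4 except for MI cDC2 (n = 3).

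The first principal component of log2 CPM (40.5% of variance) set cDC1 libraries (96.8 to 131) apart from macrophages (-84 to -72), with moDCs and cDC2 between. The second (13.4%) ordered macrophages, moDCs and cDC2. The third (8.77%) lay at -18.4 to -49.1 in all MI libraries and above these values in SS. In SS, libraries numbered 1 and 4 had a larger share of reads in no feature (11.6% to 16.9%) than those numbered 2 and 3 (6.42% to 9.26%).

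**Figure D1:**
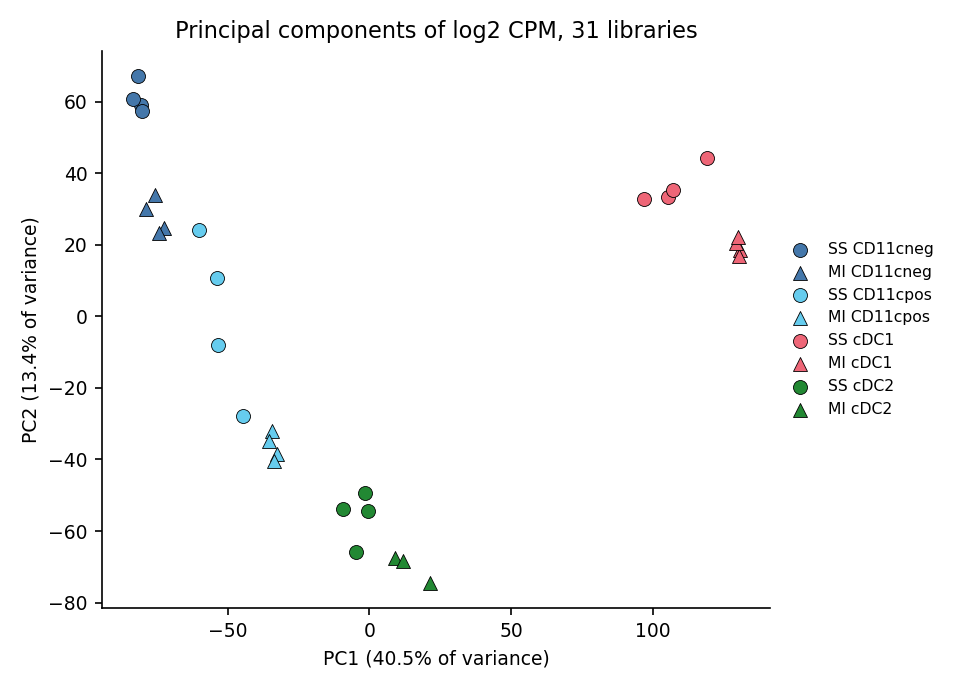
First against second principal component of log2 CPM for 31 libraries, with the share of variance on each axis; colours are cell types, circles SS and triangles MI. cDC1 libraries lie at 96.8 to 131 on the first component, apart from the other cell types.

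In macrophages the largest rise after MI was in Arg1, coding for arginase 1, by 36.4-fold (127 ± 121 against 3.47 ± 3.47 CPM, SD, n = 4, adjusted p = 0.00248), and the fibronectin gene Fn1 rose 14.4-fold (931 ± 291 against 64.6 ± 74.9, adjusted p = 0.00130). The potassium channel gene Kcnn4 rose 22.7-fold (41.2 ± 7.68 against 1.81 ± 1.25, adjusted p = 1.56e-11), and its MI effect differed among the cell types (adjusted p = 8.16e-09). The other largest rises were Arhgap24 (34.7-fold, adjusted p = 1.20e-05), Saa3 (28.3-fold, 0.0303), Spon1 (16.7-fold, 6.17e-05), Ikbke (14.1-fold, 1.75e-04) and Adam8 (13.1-fold, 5.40e-07). The largest falls were in the receptor genes Clec4f (32.7-fold, adjusted p = 0.00218), Cd207 (30.9-fold, 8.62e-09) and Vsig4 (18.1-fold, 2.89e-07), of which Cd207 codes for langerin and went to 15.3 against 474 CPM. Hepacam2 (12.7-fold), Hspb1 (10.8-fold), Tspan8 (9.03-fold), Hspa1b (8.94-fold) and Dmpk (8.85-fold) fell as well. Lead positions are Arg1 at 24915221 to 24927484 on chromosome 10 (minus strand), Fn1 at 71585520 to 71653200 on chromosome 1 (minus strand), Kcnn4 at 24370263 to 24386690 on chromosome 7 (plus strand) and Cd207 at 83671215 to 83677857 on chromosome 6 (minus strand). Folds moved by over 1.5 times without MI replicate 2 (Arg1 19.3, Saa3 15.7), SS replicate 4 (Arg1 71.3, Fn1 33.9), SS replicate 3 (Saa3 276), SS replicate 2 (Spon1 29.4) and MI replicate 1 (Clec4f 61.6).

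Of 13039 genes tested, 963 changed in macrophages, 523 up and 440 down (54.3% up), and 217 and 235 of them by at least 2-fold. With upper-quartile factors 396 rose and 604 fell (39.6% up), so the balance of directions depends on the scaling. Against SS numbers 1 and 4 alone 728 genes changed, and against numbers 2 and 3 alone 1349. Arg1 did not pass against numbers 1 and 4 (adjusted p = 0.0729), nor Hspb1 against 2 and 3 (0.107). Saa3, an acute-phase gene, did not pass without any one of MI replicate 2 (0.118) and SS replicates 1 (0.0784), 2 (0.0937) and 4 (0.0698). MI replicate 2 was the highest of the MI macrophage libraries for Arg1 (306.7 CPM), Fn1 (1363 CPM), Adam8 (148.5 CPM) and Saa3 (110.9 CPM), and it was also the highest in summed mural transcripts (37.7 CPM).

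Of glycolysis and hypoxia genes in macrophages, 14 of 25 rose, 0 fell and 11 did not pass (16 up and 1 down adjusted over the list alone, list adjusted p = 5.30e-10, 0.0640 with estimated correlation). The growth factor gene Vegfa rose 11.3-fold (59.2 ± 27.1 against 5.22 ± 2.93, adjusted p = 1.98e-05) and Ndrg1 and Ero1l rose 7.61-fold and 1.996-fold. Of tissue repair genes, 8 of 24 rose, 0 fell and 16 did not pass (11 up and 1 down adjusted over the list alone, list adjusted p = 3.96e-06, 0.0679 with estimated correlation). Beside Arg1 and Fn1 these included Mmp14 (10.6-fold, adjusted p = 2.91e-07) and Lgals3 (3.35-fold, 2.50e-05). Of classical monocyte genes, 5 of 14 rose, 0 fell and 9 did not pass (7 up and 1 down adjusted over the list alone, list adjusted p = 3.18e-05, 0.179 with estimated correlation). The rises took in the chemokine receptor gene Ccr2 (2125 ± 248 against 420.2 ± 63.4, 5.06-fold, adjusted p = 2.00e-13) and Ms4a4c (2.92-fold). Of resident macrophage genes, 0 of 25 rose, 8 fell and 17 did not pass (0 up and 10 down adjusted over the list alone, list adjusted p = 3.65e-05, 0.0679 with estimated correlation). Cd163, a scavenger receptor gene, fell 3.97-fold (129 ± 34.2 against 511 ± 85.3, adjusted p = 1.10e-06), Timd4 fell 5.49-fold (adjusted p = 1.15e-05), and Lyve1, Folr2 and Cbr2 fell too.

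Of MHC class II genes in macrophages, 2 of 14 rose, 7 fell and 5 did not pass (3 up and 8 down adjusted over the list alone, list adjusted p = 0.00948, 0.454 with estimated correlation). The falls were led by H2-Ob (3.10-fold, adjusted p = 7.94e-07), H2-DMb1 (1.64-fold, 0.00231) and H2-DMa (1.53-fold, 0.00255) and took in H2-Aa, H2-Ab1 and H2-Eb1, while the protease genes Lgmn and Ctss rose. Of type I interferon genes, 6 of 28 rose, 0 fell and 22 did not pass (9 up and 0 down adjusted over the list alone, list adjusted p = 0.00430, 0.438 with estimated correlation). Ahead were Ifit2 (3.35-fold, adjusted p = 6.76e-05), Rsad2 (2.43-fold, 0.00339) and Zbp1 (1.83-fold, 0.00687). Rsad2 did not pass against SS numbers 1 and 4 (0.0593), nor Zbp1 against 2 and 3 (0.0827). Of NF-kB genes, 6 of 23 rose, 1 fell and 16 did not pass (8 up and 2 down adjusted over the list alone, list adjusted p = 0.0145, 0.412 with estimated correlation). Ccrl2 (1.80-fold) and Ccl3 (2.07-fold) rose with Ptgs2 and Nlrp3, whereas Il1a (2.87-fold) fell, and Ccl3 did not pass against SS numbers 1 and 4 (0.0936). The cytokine gene Osm (2.32-fold, adjusted p = 7.86e-04) rose, and the costimulatory gene Cd86 (1.99-fold, adjusted p = 1.64e-04) fell.

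The dendritic cell marker gene Itgax, which codes for CD11c, rose 5.45-fold in the CD11c-negative sort (40.9 ± 15.8 against 7.5 ± 2.91, adjusted p = 9.52e-08), and of shared dendritic cell genes 4 of 12 rose, 0 fell and 8 did not pass (5 up and 0 down adjusted over the list alone, list adjusted p = 0.00318, 0.167 with estimated correlation). The lysosomal protease gene Ctsd (4.82-fold, adjusted p = 1.39e-05) and the Fc receptor gene Fcgr4 (2.16-fold, adjusted p = 0.00153) rose. The lipid efflux gene Abcg1 rose 3.33-fold (adjusted p = 5.37e-07) with Abca1 and Pparg, while Cd36 fell 3.73-fold (adjusted p = 5.84e-06) with Mfge8. Of cholesterol synthesis genes, 0 of 22 rose, 3 fell and 19 did not pass (0 up and 5 down adjusted over the list alone, list adjusted p = 0.00948, 0.358 with estimated correlation). Of immediate early and heat shock genes, 1 of 23 rose, 7 fell and 15 did not pass (2 up and 7 down adjusted over the list alone, list adjusted p = 0.00948, 0.5997 with estimated correlation). Among identity genes, Irf4 (2.14-fold) and Mgl2 (4.40-fold) of the cDC2 list and Batf3 (2.35-fold) of the cDC1 list fell, and Itgam (1.90-fold) and Naaa (1.62-fold) rose.

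Lists with no call (list adjusted p from 0.104 to 0.9998) were monocyte-macrophage identity (3 up and 0 down of 14), cell cycle (0 up and 1 down of 31) and cDC2 identity (1 up and 4 down of 12, or 1 and 5 adjusted over the list alone). The next were oxidative phosphorylation (1 up and 0 down of 32), T cell cytokine (1 up and 1 down of 17) and MHC class I (0 up and 0 down of 17). Then came maturation (0 up and 1 down of 24), efferocytosis (4 up and 4 down of 20, or 4 and 5 adjusted over the list alone) and interferon gamma (0 up and 0 down of 20). Last came cDC1 identity (2 up and 2 down of 16, or 3 and 3 adjusted over the list alone). Median, mean and test differed in sign for MHC class I (median -0.00328, mean 0.0478, test up), maturation (median 0.0494, mean -0.0385, test down), interferon gamma (median -0.0461, mean 0.0859, test down), efferocytosis (median 0.23, mean -0.0196, test up) and cDC1 identity (median 0.24, mean -0.45, test up).

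**Figure D2:**
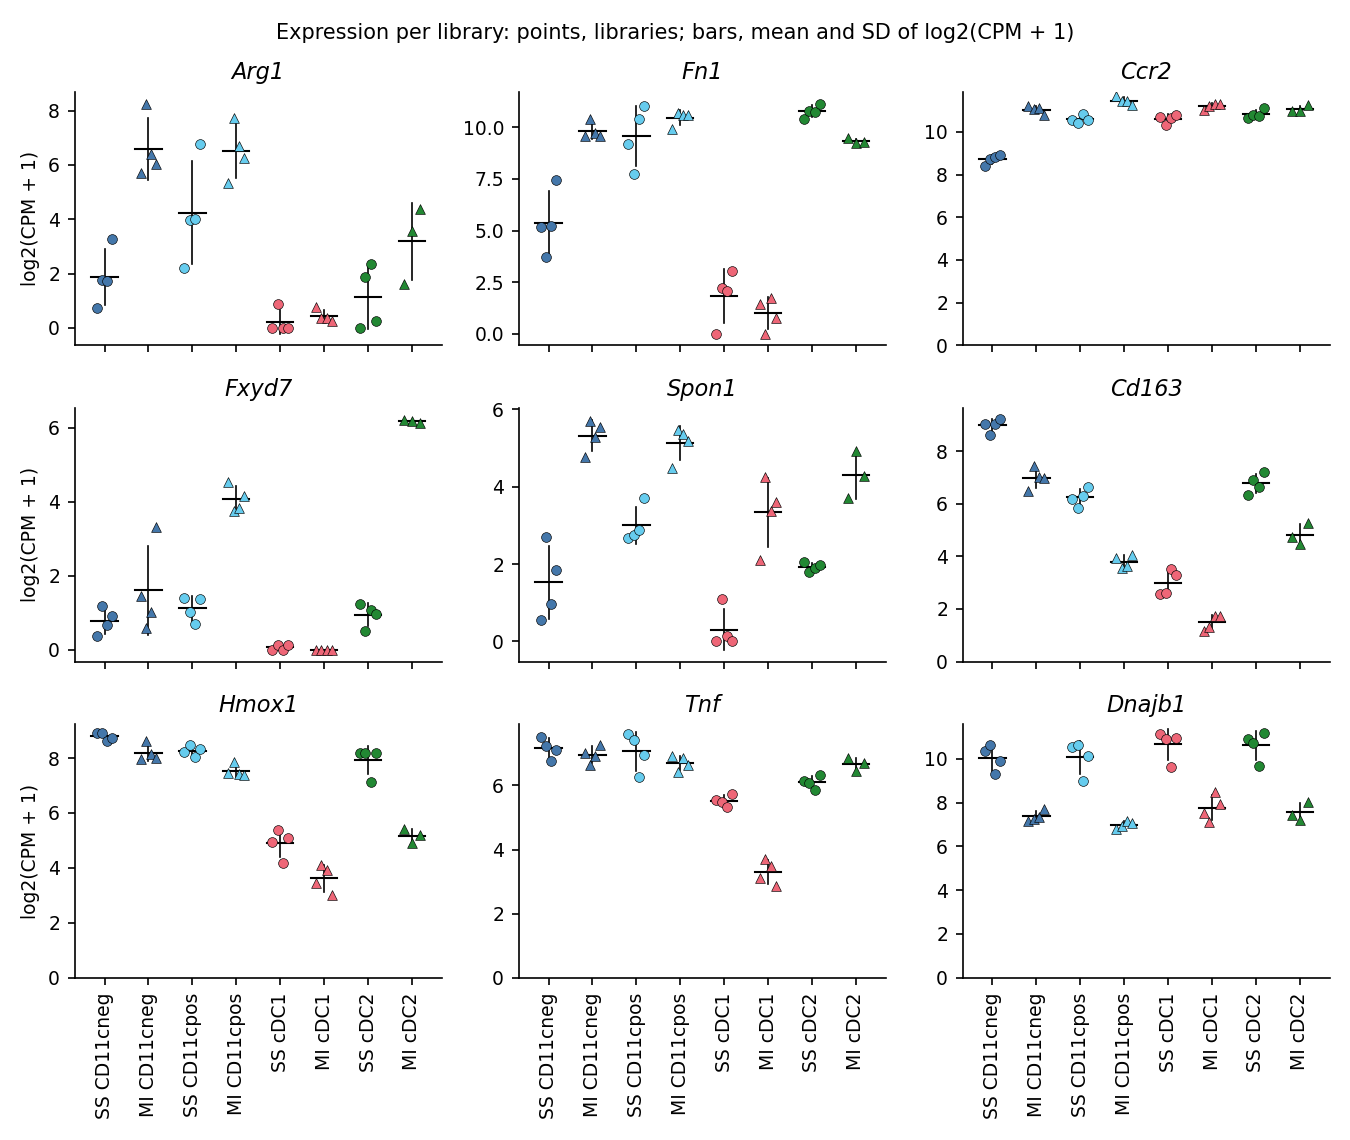
Expression of 9 genes per library, as log2(CPM + 1), in 8 groups; points are libraries and bars mean and SD. Arg1, Fn1 and Ccr2 rose and Cd163 fell in MI macrophages, Fxyd7 rose in MI cDC2 and MI moDCs, Tnf fell in MI cDC1, and Dnajb1 fell in all 4 MI groups.

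In moDCs more genes fell than rose after MI. The largest rise was in Fxyd7, a regulator of the sodium pump (16.2 ± 4.36 against 1.21 ± 0.486 CPM, n = 4, 13.3-fold, adjusted p = 1.36e-04). Other large rises were in the repressor gene Zbtb18 (5.98-fold, adjusted p = 2.63e-05), the serotonin receptor gene Htr7 (4.50-fold, adjusted p = 5.90e-04) and Spon1 (4.72-fold, adjusted p = 0.0144). Of the falls, Notch3 had 1 read in the 4 MI libraries and fell 803-fold by summed counts (interval 144 to 31756), with Tinagl1 (65.8-fold), Ltbp4 (61.3-fold), Acta2 (1.32 ± 0.884 against 70.3 ± 62.0, 53.1-fold, adjusted p = 7.66e-04) and Steap4 (43.0-fold). S100a9, a neutrophil gene, fell 373-fold (0.0991 ± 0.198 against 41.3 ± 53.1), and Hspb1 39.7-fold. In the same libraries mural genes summed to 15.7 against 125 CPM and endothelial genes to 62.5 against 189.7, MI against SS. Lead positions are Fxyd7 at 31042513 to 31051467 on chromosome 7 (minus strand), Notch3 at 32120820 to 32166852 on chromosome 17 (minus strand) and S100a9 at 90692632 to 90695721 on chromosome 3 (minus strand). Leaving out 1 library moved folds by over 1.5 times, namely without MI replicate 3 (Notch3 at least 201, Steap4 at least 109), SS replicate 2 (Notch3 265, Tinagl1 31.2, Acta2 30.2), SS replicate 3 (S100a9 142, Steap4 26.4), MI replicate 4 (Tinagl1 at least 146) and MI replicate 1 (Ltbp4 167).

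In moDCs 631 genes changed, 198 up and 433 down, and 53 and 325 by at least 2-fold. Against SS numbers 1 and 4 alone 423 changed and against 2 and 3 alone 810. Without SS replicate 2 (highest mural sum) 407 changed. With mural and endothelial CPM (with Acta2) as a covariate, which parts SS from MI, 124 changed (26 up, 98 down). Calls of Fxyd7, Spon1, Notch3, S100a9, Tinagl1, Ltbp4 and Acta2 (adjusted p 0.0536 to 0.302) ended. Spon1 did not pass without any one of SS replicates 1 (0.0523) and 2 (0.0583), nor S100a9 against SS numbers 1 and 4 (0.0826).

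Resident macrophage genes had a median log2 change of -0.87 in moDCs: 0 of 25 rose, 10 fell and 15 did not pass (0 up and 14 down adjusted over the list alone, list adjusted p = 3.54e-09, 0.0167 with estimated correlation). Cd163 fell 5.81-fold (13.1 ± 2.27 against 76.4 ± 17.7, adjusted p = 7.54e-08), Hpgd 13.7-fold and Vsig4 12.0-fold. Of glycolysis and hypoxia genes, 5 of 25 rose, 0 fell and 20 did not pass (10 up and 0 down adjusted over the list alone, list adjusted p = 5.74e-06, 0.179 with estimated correlation). The rises were led by Ndrg1 (2.55-fold, adjusted p = 3.84e-05), Ero1l (1.66-fold, 0.00234) and Bnip3 (1.63-fold, 0.00267). Ero1l did not pass against SS numbers 1 and 4 (0.111), nor Bnip3 against 2 and 3 (0.0735). Of immediate early and heat shock genes, 0 of 23 rose, 9 fell and 14 did not pass (0 up and 13 down adjusted over the list alone, list adjusted p = 3.54e-09, 0.172 with estimated correlation). Dnajb1 fell 9.19-fold (127 ± 13.3 against 1163 ± 478), Hspa1b 12.1-fold and Dnaja1 3.13-fold, and Jun and Ier5 fell too. With the mural and endothelial covariate the calls of Ero1l and Bnip3 (adjusted p 0.0714 to 0.283) ended.

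Of T cell polarising cytokine genes in moDCs, 1 of 17 rose, 3 fell and 13 did not pass (the same counts adjusted over the list alone, list adjusted p = 0.0213, 0.252 with estimated correlation). Il1a (4.01-fold, adjusted p = 1.42e-05) and Ebi3 (2.22-fold, 5.13e-05) fell and Tnfsf9 rose. Of interferon gamma genes, 0 of 20 rose, 2 fell and 18 did not pass (the same counts adjusted over the list alone, list adjusted p = 0.0163, 0.358 with estimated correlation). The 2 were Iigp1 (3.25-fold, adjusted p = 0.00567) and Gbp4 (2.56-fold, 0.0119), the latter not passing without any one of MI replicates 1 (0.0527) and 2 (0.0532) and SS replicate 1 (0.0558). Of the maturation genes, Ccr7 (log2 change 1.46, adjusted p = 0.295), Fscn1 (1.81, 0.207) and Ccl22 (0.51, 0.809) did not pass, Ebi3 (2.22-fold) fell and Tnfrsf9 rose. The calls of Iigp1 and Gbp4 (adjusted p 0.256 to 0.469) ended with the mural and endothelial covariate.

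Among monocyte and macrophage genes of moDCs, Ccr2 rose 1.83-fold (2828 ± 377 against 1542 ± 206, adjusted p = 4.23e-05) while the monocyte gene F13a1 fell 3.55-fold (adjusted p = 4.04e-05). Mmp14 (2.52-fold, adjusted p = 0.0115) and Tgfbi (1.76-fold, 1.01e-05) rose, Cd36 (3.75-fold, adjusted p = 1.01e-05), Gas6 (2.74-fold, 5.53e-05) and Icam1 (1.94-fold, 0.00409) fell, and so did the interferon gene Oasl1 (2.24-fold), while Ifit2 (2.46-fold) rose but did not pass against SS numbers 1 and 4 (0.0757). Of cholesterol synthesis genes, 0 of 22 rose, 3 fell and 19 did not pass (the same counts adjusted over the list alone, list adjusted p = 0.00948, 0.358 with estimated correlation). The cDC1 markers Clec9a (7.34-fold), Tlr11 (2.52-fold) and Batf3 fell, and Naaa (1.48-fold) rose. Clec9a did not pass against SS numbers 1 and 4 (0.149) nor Tlr11 against 2 and 3 (0.139). Icam1, Clec9a and Tlr11 did not pass when only moDC samples were fitted (0.0532, 0.0857 and 0.0588). With the mural and endothelial covariate the calls of Mmp14, Gas6, Icam1, Oasl1, Ifit2, Naaa and Clec9a (adjusted p 0.0663 to 0.341) ended. Without MI replicate 3 the fold of Clec9a was 15.8.

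Lists with no call (list adjusted p from 0.179 to 0.9998) were tissue repair (2 up and 2 down of 24, or 2 and 3 adjusted over the list alone), shared dendritic cell (1 up and 0 down of 12, or 2 and 2 adjusted over the list alone), oxidative phosphorylation (0 up and 0 down of 32) and efferocytosis (1 up and 3 down of 20, or 2 and 3 adjusted over the list alone). The next were MHC class I (0 up and 0 down of 17), maturation (1 up and 3 down of 24, or 2 and 3 adjusted over the list alone), NF-kB (0 up and 3 down of 23) and cDC2 identity (0 up and 0 down of 12, or 0 and 2 adjusted over the list alone). Then came type I interferon (1 up and 1 down of 28), classical monocyte (1 up and 1 down of 14, or 2 and 5 adjusted over the list alone), cell cycle (0 up and 0 down of 31) and cDC1 identity (1 up and 3 down of 16, or 2 and 3 adjusted over the list alone). Last came MHC class II (1 up and 1 down of 14, or 3 and 2 adjusted over the list alone) and monocyte-macrophage identity (1 up and 0 down of 14). Median, mean and test differed in sign for MHC class II (median -0.17, mean 0.12, test up), type I interferon (median -0.0489, mean 0.0176, test up), NF-kB (median 5.35e-04, mean -0.183, test down), cell cycle (median -0.13, mean -0.0915, test up), efferocytosis (median 0.0150, mean -0.32, test down), cDC1 identity (median -0.32, mean -0.40, test up) and monocyte-macrophage identity (median -0.31, mean -0.11, test up).

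In cDC1, the largest changes after MI were falls of genes to 0 reads. Ltbp4 went to 0 reads in the 4 MI libraries from 38.3 ± 29.3 CPM in SS (SD, n = 4, at least 515-fold, adjusted p = 6.22e-05). Bcam (at least 368-fold), Sorbs2 (at least 198-fold), Jam2 (at least 194-fold), Rgs4 (at least 187-fold), Olfr558 (at least 164-fold), Tinagl1 (at least 158-fold) and Ptprb (at least 137-fold) also fell to 0 reads. In the same libraries the summed mural genes stood at 2.01 ± 0.973 against 163 ± 91.2 CPM in MI against SS and the endothelial genes at 11.1 ± 3.19 against 113 ± 80.3. Rises were smaller. The matrix gene Spon1 rose 35.4-fold (10.5 ± 6.07 against 0.309 ± 0.554, adjusted p = 2.85e-05), followed by Ifitm1 (9.55-fold, adjusted p = 0.0256), Lpar1 (6.14-fold, 1.23e-06), Emb (4.57-fold, 4.83e-09), Flot1 (4.56-fold, 1.25e-08), Wfdc17 (4.49-fold, 1.27e-08), Dab2 (4.22-fold, 0.00412) and Dok3 (4.15-fold, 3.41e-05). Lead positions are Spon1 at 113765998 to 114043370 on chromosome 7 (plus strand), Ltbp4 at 27305136 to 27337692 on chromosome 7 (minus strand) and Bcam at 19756131 to 19771016 on chromosome 7 (minus strand). Some folds moved by over 1.5 times without SS replicate 2 (Spon1 389, Bcam at least 231) and SS replicate 1 (Sorbs2 at least 303).

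In cDC1 1158 genes changed, 281 up and 877 down, and 82 and 677 by at least 2-fold. Against SS numbers 1 and 4 alone 974 changed and against 2 and 3 alone 937. With mural and endothelial CPM as a covariate, which nearly follows state in this cell type, 34 changed (8 up, 26 down), and the calls of Ltbp4, Jam2, Spon1, Ifitm1, Lpar1, Emb, Dab2, Sorbs2, Rgs4, Tinagl1, Olfr558 and Ptprb (adjusted p 0.131 to 0.871) ended. Ifitm1, an interferon-inducible gene, did not pass without any one of MI replicate 2 (0.0632) and SS replicates 1 (0.0709), 3 (0.0745) and 4 (0.0549). Dab2 did not pass when only cDC1 samples were fitted (0.232).

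Of the maturation genes in cDC1, 0 of 24 rose, 7 fell and 17 did not pass (0 up and 11 down adjusted over the list alone, list adjusted p = 2.71e-06, 0.348 with estimated correlation). Ebi3 (2.34-fold, adjusted p = 1.10e-05), Icosl (2.55-fold, 4.35e-04) and Cd80 (2.35-fold, 0.00195) came first, with Cd83, Ccl17 and Ccl5, while Ccr7 (log2 change -1.11, adjusted p = 0.433), Cd40 (-0.74, 0.0515) and Cd86 (-0.0625, 0.904) did not pass. Of T cell polarising cytokine genes, 1 of 17 rose, 8 fell and 8 did not pass (2 up and 10 down adjusted over the list alone, list adjusted p = 1.20e-04, 0.0513 with estimated correlation). The cytokine gene Tnf fell 4.97-fold (9.05 ± 2.60 against 45.1 ± 5.54, adjusted p = 2.89e-08) and Tnfsf9 fell 2.80-fold (adjusted p = 2.33e-05), with Il6, Osm and Dll4, whereas Il1b rose. Of NF-kB genes, 1 of 23 rose, 9 fell and 13 did not pass (1 up and 12 down adjusted over the list alone, list adjusted p = 3.96e-06, 0.0793 with estimated correlation). The falls included Nfkbia (2.70-fold, adjusted p = 2.37e-08) and Nfkbiz (4.89-fold, 1.53e-06), Icam1 and Tnfaip3. The interferon gamma genes Irf1 (2.54-fold, adjusted p = 9.21e-05) and Gbp2 (4.68-fold, 9.34e-05) fell, as did Gbp4 (2.77-fold), which did not pass against SS numbers 1 and 4 (0.178) or with only cDC1 samples fitted (0.0555). Tap1, a peptide transporter gene of MHC class I presentation, rose 1.38-fold (adjusted p = 0.00378), and Lgmn, a protease of the class II pathway, rose 2.32-fold (adjusted p = 5.37e-06). In the same libraries T cell genes summed to 1.77 against 8.82 CPM and NK and ILC genes to 14.6 against 38.4, MI against SS, beside the mural and endothelial sums above. With the mural and endothelial covariate the calls of Ebi3, Icosl, Cd80, Tnf, Tnfsf9, Nfkbia, Nfkbiz, Irf1, Gbp2, Gbp4 and Tap1 (adjusted p 0.0542 to 0.991) ended. Without MI replicate 1 the fold of Gbp4 was 4.44.

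Of resident macrophage genes in cDC1, 0 of 25 rose, 11 fell and 14 did not pass (0 up and 15 down adjusted over the list alone, list adjusted p = 5.55e-10, 0.0167 with estimated correlation). The median log2 change was -1.72. Gas6 fell to 0 reads (at least 122-fold, adjusted p = 1.51e-10), Adgre1 fell 3.10-fold (7.84 ± 2.56 against 24.2 ± 4.56) and Cd163 3.87-fold. Of monocyte-macrophage identity genes, 0 of 14 rose, 6 fell and 8 did not pass (the same counts adjusted over the list alone, list adjusted p = 2.14e-04, 0.0513 with estimated correlation). The falls took in Csf1r (1.95-fold, adjusted p = 2.73e-04) and Lyz2 (2.07-fold, 2.52e-04). Of efferocytosis genes, 3 of 20 rose, 9 fell and 8 did not pass (3 up and 10 down adjusted over the list alone, list adjusted p = 3.28e-04, 0.0640 with estimated correlation). Mfge8 fell 5.42-fold and Axl 4.37-fold, and Pparg and Abcg1 rose. Of cDC2 identity genes, 0 of 12 rose, 5 fell and 7 did not pass (0 up and 6 down adjusted over the list alone, list adjusted p = 0.00169, 0.0254 with estimated correlation). The falls were led by Cd209a (6.44-fold, adjusted p = 5.48e-05), Itgam (1.75-fold, 0.00316) and Esam (13.5-fold, 0.00214). Of the 16 cDC1 identity genes 0 passed by edgeR (list adjusted p = 0.298), and Clec9a stood at 196 ± 9.48 against 188 ± 12.7 CPM. Ccr2 rose 1.49-fold (adjusted p = 0.00339), which ended against SS numbers 1 and 4 (0.0777), while F13a1 (5.30-fold) and Ly6c1 (17.4-fold) fell. Plau (3.12-fold, adjusted p = 8.58e-06) and Hmox1 (2.56-fold, 5.69e-04) fell and Mmp14 (2.67-fold) rose. With the mural and endothelial covariate the log2 changes of Esam and Ly6c1 reversed to 0.86 and 0.27, and the calls of Adgre1, Cd163, Csf1r, Lyz2, Mfge8, Axl, Cd209a, Itgam, Ccr2, F13a1, Plau, Hmox1 and Mmp14 (adjusted p 0.0629 to 0.989) ended. F13a1 (0.109) and Itgam (0.0636) also did not pass when only cDC1 samples were fitted. Without MI replicate 3 the fold of F13a1 was 9.80 and without SS replicate 2 the fold of Esam was 8.19.

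The median log2 change of cell cycle genes in cDC1 was 0.24: 0 of 31 rose, 0 fell and 31 did not pass (the same counts adjusted over the list alone, list adjusted p = 0.0213, 0.742 with estimated correlation). The median of oxidative phosphorylation genes was 0.19: 0 of 32 rose, 0 fell and 32 did not pass (the same counts adjusted over the list alone, list adjusted p = 3.33e-04, 0.5997 with estimated correlation). Of immediate early and heat shock genes, 1 of 23 rose, 9 fell and 13 did not pass (3 up and 10 down adjusted over the list alone, list adjusted p = 0.0457, 0.702 with estimated correlation). Dnajb1 (7.51-fold, adjusted p = 1.06e-05) and Jund (1.77-fold, 4.47e-05) fell and Ier3 (2.31-fold, adjusted p = 2.33e-05) rose, calls that ended with the mural and endothelial covariate (adjusted p 0.410 to 0.601).

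Lists with no call (list adjusted p from 0.0614 to 0.824) were tissue repair (1 up and 5 down of 24, or 1 and 7 adjusted over the list alone), cholesterol synthesis (0 up and 1 down of 22) and interferon gamma (1 up and 5 down of 20, or 1 and 6 adjusted over the list alone). The next were type I interferon (3 up and 1 down of 28, or 5 and 4 adjusted over the list alone), cDC1 identity (0 up and 0 down of 16) and classical monocyte (3 up and 2 down of 14, or 3 and 3 adjusted over the list alone). Then came glycolysis (1 up and 2 down of 25), shared dendritic cell (0 up and 0 down of 12) and MHC class I (1 up and 1 down of 17). Last came MHC class II (2 up and 1 down of 14). Median, mean and test differed in sign for MHC class II (median -0.14, mean -1.22e-04, test up) and MHC class I (median -0.00448, mean -0.00741, test up).

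In cDC2 (n = 3 after MI, n = 4 in SS), the largest rise was in Fxyd7, as in moDCs. It rose 73.6-fold (71.5 ± 2.06 against 0.958 ± 0.398 CPM, adjusted p = 1.43e-07). The interferon-inducible Ifitm1 rose 31.8-fold (197 ± 106 against 6.17 ± 2.65, adjusted p = 4.30e-04), Arhgap24 28.5-fold (adjusted p = 7.07e-06) and the transporter gene Slc16a14 23.96-fold (adjusted p = 6.96e-04). Gpnmb (16.8-fold, adjusted p = 0.0122), Ffar2 (16.0-fold, 0.00587), Enpp1 (15.1-fold, 5.28e-08) and Cdh1 (11.4-fold, 0.00157) followed. The granzyme gene Gzma fell to 0 reads (at least 113-fold, adjusted p = 3.45e-05), and Hspb1 (40.9-fold, adjusted p = 7.55e-04), Cxcl12 (36.8-fold, 0.00282), Pla2g2d (33.3-fold, 8.22e-04) and Fabp4 (30.1-fold, 6.74e-04) fell too. In the same libraries T cell genes summed to 2.39 against 12.8 CPM and mural genes to 8.70 against 29.99, MI against SS. Lead positions are Ifitm1 at 140967221 to 140969825 on chromosome 7 (plus strand), Cdh1 at 106603351 to 106670246 on chromosome 8 (plus strand) and Gzma at 113093825 to 113100981 on chromosome 13 (minus strand). By over 1.5 times, folds moved without SS replicate 1 (Arhgap24 66.3), MI replicate 1 (Gzma at least 74.3, Pla2g2d 21.97), MI replicate 3 (Gzma at least 75.1), SS replicate 2 (Cxcl12 18.7) and SS replicate 3 (Pla2g2d 14.5).

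In cDC2 1440 genes changed, 575 up and 865 down, and 246 and 492 by at least 2-fold. Against SS numbers 1 and 4 alone 1018 changed and against 2 and 3 alone 1942. Without MI replicate 1 882 changed and without MI replicate 2 923. Gpnmb did not pass without MI replicate 1 (0.0541). Cdh1 did not pass with DESeq2 (0.0593).

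Of MHC class II genes, 5 of 14 rose, 1 fell and 8 did not pass (5 up and 2 down adjusted over the list alone, list adjusted p = 0.0461, 0.5997 with estimated correlation) in cDC2. The class II transactivator gene Ciita rose 2.09-fold (332 ± 26.4 against 159 ± 34.0, adjusted p = 6.89e-04) and H2-Oa 3.03-fold (adjusted p = 0.00275), with H2-Ob, Lgmn and Ifi30, while H2-DMa fell 1.52-fold but not without MI replicate 1 (0.0584). The MI effects of Ciita and H2-Oa in the test of a difference among the cell types had adjusted p = 0.0151 and 0.169. The costimulatory gene Cd86 rose 1.74-fold (205 ± 23.5 against 118 ± 15.4, adjusted p = 0.00254) and Tnfrsf9 8.00-fold (adjusted p = 0.0117), the latter not passing without MI replicate 1 (0.0965), while Ccr7 (log2 change 0.66, adjusted p = 0.659), Cd40 (0.0395, 0.960) and Cd80 (-0.28, 0.584) did not pass. Il1a (4.95-fold, adjusted p = 4.81e-06), Il6 (9.53-fold, 1.72e-04) and Il18 (2.18-fold, 0.00527) fell, and Tnfsf9 and Osm rose. Il18 did not pass against SS numbers 1 and 4 (0.0830). Of interferon gamma genes, 1 of 20 rose, 6 fell and 13 did not pass (the same counts adjusted over the list alone, list adjusted p = 0.0187, 0.366 with estimated correlation). Gbp4 (3.61-fold, adjusted p = 0.00108) fell, with Cxcl9 and Irf1. Type I interferon genes went both ways, with Oasl1 (4.06-fold, adjusted p = 2.21e-06) and Cxcl10 (3.29-fold, 0.00112) falling and Ifit1 (3.84-fold, adjusted p = 7.24e-05) rising. Without MI replicate 1 the fold of Tnfrsf9 was 5.23 and without SS replicate 3 the fold of Tnfrsf9 was 15.4.

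Of resident macrophage genes in cDC2, 2 of 25 rose, 17 fell and 6 did not pass (2 up and 20 down adjusted over the list alone, list adjusted p = 5.72e-09, 0.0167 with estimated correlation). Hpgd fell 22.9-fold (4.23 ± 2.14 against 97.1 ± 32.6, adjusted p = 2.13e-06), Cd163 3.95-fold and Adgre1 2.78-fold, with C1qa, C1qb and C1qc. Of classical monocyte genes, 0 of 14 rose, 5 fell and 9 did not pass (0 up and 6 down adjusted over the list alone, list adjusted p = 0.00189, 0.358 with estimated correlation). The falls took in F13a1 (9.68-fold, adjusted p = 3.83e-08), Thbs1 (8.58-fold, 5.82e-04) and Ly6c2 (57.0-fold, 0.00112). Of monocyte-macrophage identity genes, 1 of 14 rose, 7 fell and 6 did not pass (2 up and 9 down adjusted over the list alone, list adjusted p = 0.00433, 0.126 with estimated correlation). The lysozyme gene Lyz2 (5.65-fold, adjusted p = 2.68e-09) fell. Of efferocytosis genes, 2 of 20 rose, 6 fell and 12 did not pass (the same counts adjusted over the list alone, list adjusted p = 0.0444, 0.358 with estimated correlation). Cd36 (14.3-fold, adjusted p = 1.37e-09) and Pparg (2.73-fold, 8.73e-05) fell. The heme oxygenase gene Hmox1 fell 7.18-fold (35.3 ± 6.04 against 254 ± 75.4, adjusted p = 4.05e-08) and Ecm1 (7.58-fold, adjusted p = 5.54e-07) fell, while Tgfbi (2.08-fold, adjusted p = 1.22e-07), Spp1 and Mmp14 rose. The cDC1 marker Clec9a fell 24.9-fold (0.389 ± 0.385 against 9.89 ± 0.919, adjusted p = 3.02e-05), with Batf3 (2.28-fold) and Tlr11 (3.81-fold). Folds also moved by over 1.5 times without MI replicate 3 (Thbs1 13.3, Ly6c2 164, Clec9a 48.2) and MI replicate 1 (Clec9a 16.5).

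Of cholesterol synthesis genes, 0 of 22 rose, 8 fell and 14 did not pass (the same counts adjusted over the list alone, list adjusted p = 1.07e-04, 0.140 with estimated correlation) in cDC2. Insig1 (2.01-fold, adjusted p = 3.23e-05) and Stard4 (2.55-fold, 6.73e-04) were among those that fell. Of cell cycle genes, 2 of 31 rose, 0 fell and 29 did not pass (5 up and 0 down adjusted over the list alone, list adjusted p = 1.07e-04, 0.568 with estimated correlation). Of the 2 that passed, Mcm2 did not pass without any one of MI replicates 1 (0.0792) and 3 (0.1002) and SS replicates 1 (0.0703) and 2 (0.0847), nor Mcm4 without any one of MI replicate 1 (0.167) and SS replicates 1 (0.0811) and 2 (0.0560). Of oxidative phosphorylation genes, 0 of 32 rose, 1 fell and 31 did not pass (0 up and 0 down adjusted over the list alone, list adjusted p = 8.68e-04, 0.644 with estimated correlation). Their median log2 change was -0.31. Of immediate early and heat shock genes, 0 of 23 rose, 8 fell and 15 did not pass (3 up and 8 down adjusted over the list alone, list adjusted p = 0.0444, 0.702 with estimated correlation). The falls were led by Dnaja1 (3.56-fold, adjusted p = 3.79e-06), Hspa8 (1.90-fold, 1.06e-05) and Dnajb1 (8.72-fold, 1.77e-05). With a replicate block the MHC class II and the immediate early and heat shock calls ended (adjusted p = 0.0517 and 0.108). Pdk1 (2.66-fold, adjusted p = 0.00282) of the glycolysis genes and Flt3 (2.87-fold, adjusted p = 1.82e-04) rose, and Rab7b (2.59-fold, adjusted p = 1.78e-04) fell.

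Lists with no call (list adjusted p from 0.0682 to 0.670) were shared dendritic cell (2 up and 1 down of 12, or 4 and 1 adjusted over the list alone), MHC class I (0 up and 3 down of 17, or 1 and 4 adjusted over the list alone) and T cell cytokine (2 up and 5 down of 17, or 3 and 5 adjusted over the list alone). The next were maturation (2 up and 0 down of 24), type I interferon (3 up and 5 down of 28) and cDC1 identity (1 up and 4 down of 16, or 5 and 4 adjusted over the list alone). Then came tissue repair (5 up and 7 down of 24, or 7 and 8 adjusted over the list alone), cDC2 identity (0 up and 1 down of 12) and NF-kB (3 up and 6 down of 23, or 4 and 7 adjusted over the list alone). Last came glycolysis (3 up and 0 down of 25). Median, mean and test differed in sign for NF-kB (median 0.0505, mean -0.39, test down) and glycolysis (median -0.0553, mean 0.0549, test up).

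**Figure D3:**
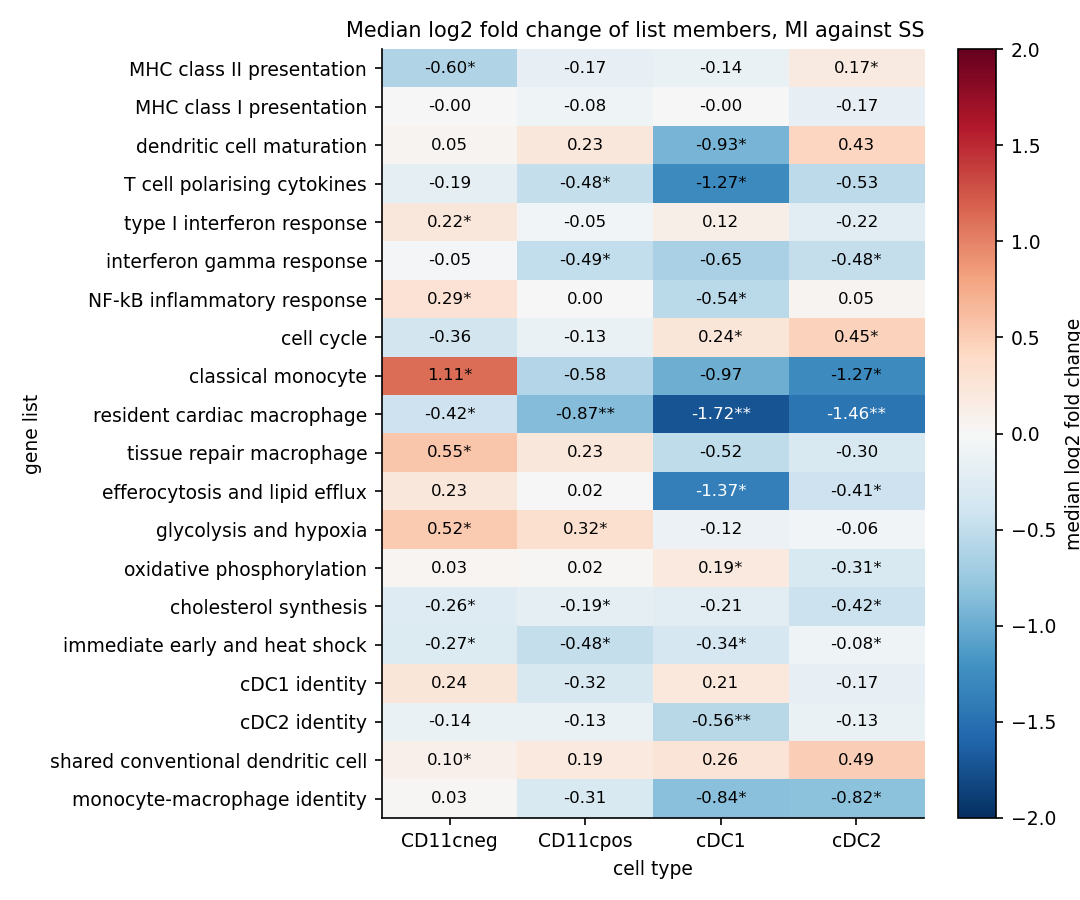
Median log2 fold change, MI against SS, of the tested members of 20 gene lists (vertical) in 4 cell types (horizontal), on a colour scale from -2 to 2. A single star marks list adjusted p under 0.05 with the preset correlation and a pair of stars also with the estimated correlation, which the resident macrophage list reached in moDCs, cDC1 and cDC2 (medians -0.87, -1.72 and -1.46).

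Changed genes overlapped between the cell types, which share no libraries. Counts for independent lists do not allow for SS libraries of the same number deviating together in macrophages and moDCs (0.119 to 0.203) and in macrophages and cDC2 (0.109 to 0.160), nor for the SS batch. Rising in both members of a pair were 108 genes in macrophages and moDCs (7.94 for independent lists of the same sizes), 89 in macrophages and cDC1 (11.3), 131 in macrophages and cDC2 (23.1), 40 in moDCs and cDC1 (4.27), 102 in moDCs and cDC2 (8.73) and 66 in cDC1 and cDC2 (12.4). Falling in both were 179 (14.6), 153 (29.6), 181 (29.2), 235 (29.1), 241 (28.7) and 272 (58.2), in the same order of pairs. Changed in opposite directions were 0, 36, 62, 15, 5 and 48. In all 4 cell types 15 genes rose and 72 fell, against 0.00755 and 0.0652 for independent lists. Among the 15 were the matrix gene Spon1, the matrix protease gene Mmp14, the kinase gene Jak3 and the interferon-inducible Ifit2. Among the 72 were Cd163, the lipid receptor gene Cd36, the langerin gene Cd207, the cytokine gene Il1a and the class II chaperone gene H2-DMa. Bcam and the NK and T cell genes Gzma, Nkg7, Il2rb and Lck were there too. With the mural and endothelial covariate 0 of the 15 and 3 of the 72 (Dok2, Id3 and Pdlim1) passed in all 4 cell types, and in cDC1, where it nearly follows state, 0 and 5 did.

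All 6 heat shock members of the immediate early and heat shock list (Hspa1a, Hspa1b, Hspa8, Hsph1, Dnaja1 and Dnajb1) were among the 72, seen by eye and not tested for enrichment. Their median log2 changes were -2.33 in macrophages, -2.33 in moDCs, -1.61 in cDC1 and -1.93 in cDC2. Medians of the 17 immediate early members were 0.0658, -0.20, 0.11 and 0.0652, and 1, 3, 3 and 2 of them fell, Jund in all 4 cell types (-0.64, -0.82, -0.82 and -0.93), while 1, 0, 1 and 0 rose. Of the 6, 0 passed the edgeR test of an MI effect differing among the cell types (adjusted p from 0.321 to 0.946).

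**Figure D4:**
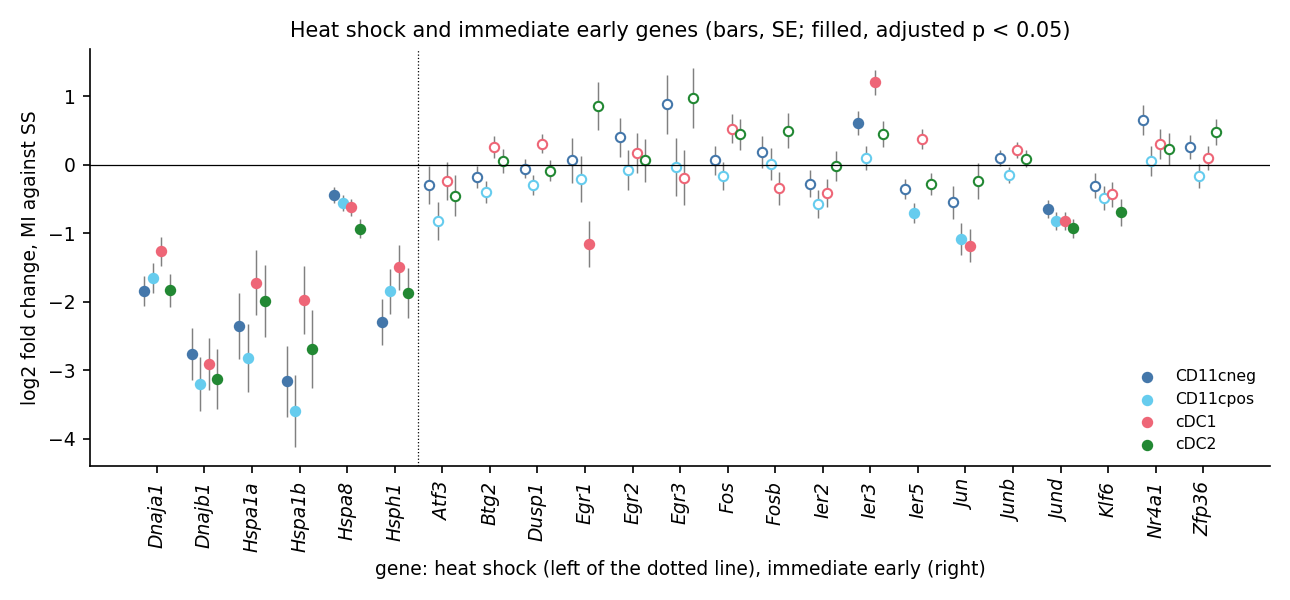
Log2 fold change ± SE, MI against SS, of 6 heat shock genes (left of the dotted line) and 17 immediate early genes (right) in 4 cell types; filled points passed at adjusted p under 0.05. All heat shock genes lie below 0, and the immediate early medians lie between -0.20 and 0.11.

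Sums of marker genes of 11 other cell types measured what else the sorted libraries held. By two-sided exact permutation tests adjusted over 44 tests 0 passed (16 had an unadjusted exact p of 0.0286, the smallest that 4 against 4 libraries allow, which is 0.0786 adjusted), so these are levels and not called changes. Mural genes, MI against SS, stood at 2.01 ± 0.973 against 163 ± 91.2 CPM in cDC1 (Acta2, 0.320 against 97.0 CPM), 15.7 against 125 in moDCs, 8.70 against 29.99 in cDC2 and 17.8 against 19.6 in macrophages. Endothelial genes stood at 11.1 against 113 in cDC1 (led by Fabp4), 62.5 against 189.7 in moDCs, 44.3 against 88.2 in cDC2 and 44.1 against 67.4 in macrophages. Cardiomyocyte genes stood at 105 ± 38.2 against 228 ± 32.3 in macrophages (Nppa, 13.6 against 44.7 CPM), 31.0 against 149.8 in moDCs, 14.1 against 51.2 in cDC1 and 9.61 against 23.5 in cDC2. Fibroblast sums were mostly Gsn, which macrophages and dendritic cells also express, at 659 against 561, 919.7 against 817, 810.2 against 958 and 1328 against 945 in macrophages, moDCs, cDC1 and cDC2.

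In the same order, neutrophil genes (led by Csf3r or Cxcr2) stood at 166 against 114, 121 against 208, 1.76 against 5.32 and 26.9 against 77.8 CPM, MI against SS. B cell genes, led by Cd79b or Ms4a1, stood at 31.3 against 34.4, 15.6 against 36.2, 3.96 against 9.49 and 9.29 against 18.5, and T cell genes at 2.53 against 6.37, 3.75 against 11.8, 1.77 against 8.82 and 2.39 against 12.8. NK and ILC genes stood at 10.3 against 13.3, 88.7 against 45.8, 14.6 against 38.4 and 64.9 against 42.5. Outside cDC1 Il7r stood at 9.96 against 1.14, 84.1 against 23.5 and 48.0 against 13.4. Plasmacytoid dendritic cell genes, led by Tcf4 or Bst2, stood at 199 against 235, 164 against 241, 125 against 116 and 164 against 146. Mast cell and basophil genes stood at 0 against 0.749, 0.02501 against 1.22, 0.421 against 2.30 and 0.165 against 2.62, and erythroid genes, all Alas2, at 0.194 against 0.484, 0.0995 against 1.25, 0.289 against 2.08 and 0.0963 against 0.998.

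**Figure D5:**
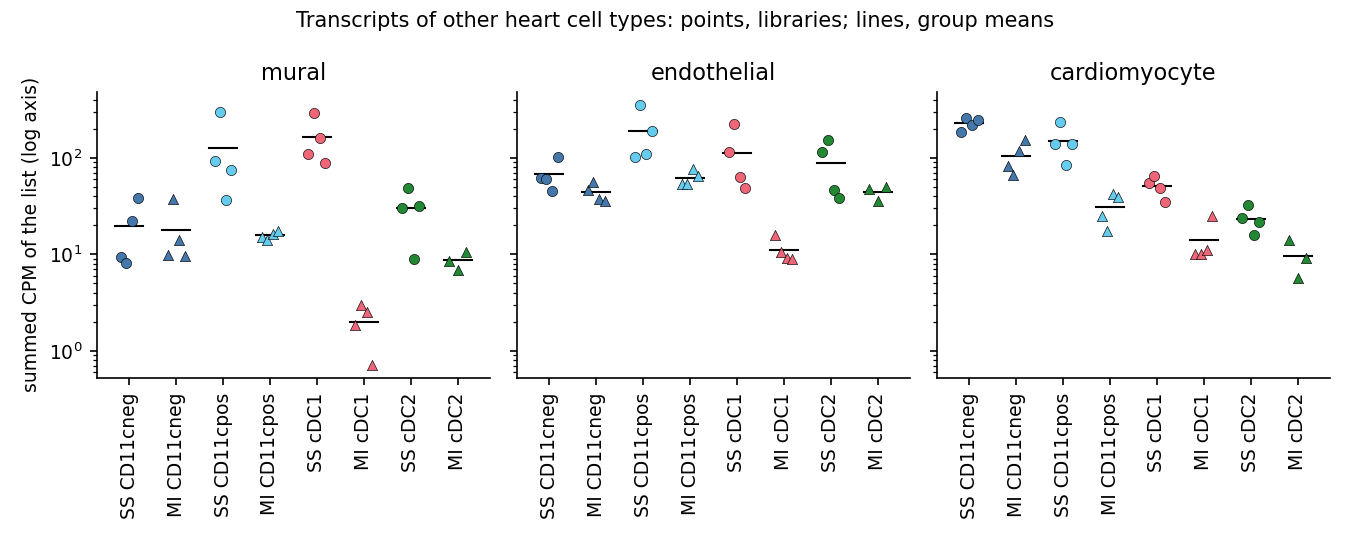
Summed CPM of mural, endothelial and cardiomyocyte marker genes per library (log axis) in 8 groups; points are libraries and lines group means. Mural CPM of cDC1 averaged 2.01 in MI and 163 in SS.

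The cell types were compared within each state to place their identities beside the effect of MI. In SS, the chemokine gene Ccl17 had 1 read over the 4 macrophage libraries and was higher in moDCs by 1362-fold by summed counts (interval 244 to 53851) (32.7 ± 9.37 CPM, n = 4, adjusted p = 3.21e-08). Ccl22 was higher by 192-fold (114 ± 66.5 against 0.587 ± 0.934, adjusted p = 6.06e-05), the chemokine receptor gene Ccr7 85.4-fold (adjusted p = 5.51e-05), Upb1 96.4-fold and the transcription factor gene Spib 59.2-fold. SS moDC replicate 3 was the highest in plasmacytoid dendritic cell genes (411 CPM, the next 200.5). With limma-voom the calls of Ccl22 (0.153), Ccr7 (0.170) and Spib (0.0568) ended. Lower in moDCs were Lyve1 (26.5-fold, adjusted p = 1.38e-07), Cbr2 (12.4-fold, 5.05e-09) and Folr2 (10.7-fold, 1.35e-09) of resident macrophages. In all 1682 genes differed, 1116 higher and 566 lower in moDCs, and within numbers 1 and 4 or 2 and 3 alone 728 and 1053. With the number as a block, these groups being paired by their correlations, 1967 differed. Folds moved by over 1.5 times without SS macrophage replicate 1 (Ccl17 at least 339, Spib 105), SS macrophage replicate 2 (Ccl22 815), SS moDC replicate 3 (Upb1 50.5, Spib 17.2) and SS macrophage replicate 4 (Upb1 at least 145).

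In SS, cDC2 against moDCs differed by 2008 genes, 959 higher and 1049 lower in cDC2 (1182 and 896 within the SS pairs). Sept3 (14.1-fold, adjusted p = 7.62e-08), Siglecg (7.97-fold, 3.94e-05) and Cldn1 (7.41-fold, 2.20e-06) were higher in cDC2, as was the lectin gene Clec4g (8.92-fold), which did not pass within numbers 1 and 4 (0.0656). The monocyte chemokine genes Ccl12 (21.5-fold, adjusted p = 2.50e-07) and Ccl8 (18.1-fold, 8.16e-05) were lower, with Cbr2 (20.4-fold, adjusted p = 7.07e-09). Leaving out 1 library moved folds by over 1.5 times, namely without SS moDC replicate 4 (Sept3 22.6) and SS cDC2 replicate 3 (Ccl12 37.3, Ccl8 107).

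In SS, cDC1 against cDC2 differed by 3675 genes, 1531 higher and 2144 lower in cDC1 (2574 and 2700 within the SS pairs). The chemokine receptor gene Xcr1 was higher by 259-fold in cDC1 (909.9 ± 104 against 3.53 ± 1.81, adjusted p = 1.93e-14), and Dkk3 218-fold. Naalad2 was higher by 899-fold by summed counts (interval 307 to 4359) and Cyp8b1 859-fold by summed counts (interval 238 to 7099), with 3 and 2 reads in the cDC2 group. The lectin gene Cd209d was lower by at least 3086-fold (0 reads against 196 ± 38.1 CPM, adjusted p = 3.61e-11). Retnla was lower by 6740.1-fold (0.743 ± 0.713 against 4601 ± 1301) and Fcrls 4572-fold. Some folds moved by over 1.5 times without SS cDC2 replicate 4 (Cyp8b1 at least 418), SS cDC2 replicate 2 (Dkk3 at least 399), SS cDC1 replicate 1 (Cd209d at least 2006) and SS cDC1 replicate 4 (Fcrls 8187).

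Of 16 cDC1 identity genes 15 were higher in cDC1 than in cDC2 and 0 lower, in SS and in MI. Of 12 cDC2 identity genes 8 were lower and 2 higher in cDC1 in either state, and of 14 monocyte-macrophage genes all 14 were lower. Of 25 resident macrophage genes 20 were lower and 0 higher in moDCs than in macrophages in SS, and 23 and 0 in MI. Of 14 classical monocyte genes 9 were higher and 1 lower in moDCs in SS, and 2 and 1 in MI. In cDC2 against moDCs, 9 of 14 monocyte-macrophage genes were lower in SS and 12 in MI, and of 12 shared dendritic cell genes 9 were higher and 1 lower in SS, and 10 and 1 in MI. After MI 1411 genes differed between moDCs and macrophages (867 higher, 544 lower), 1323 between cDC2 and moDCs (585 and 738) and 3494 between cDC1 and cDC2 (1378 and 2116). Without MI cDC2 replicate 2 the second count was 792.

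Differences of the MI effect were tested for 3 neighbouring pairs. Between moDCs and macrophages 38 genes differed (9 higher and 29 lower in moDCs, 24 and 42 against the SS pairs alone). Without MI moDC replicate 1 the count was 21, and it was 24 without any one of MI macrophage replicate 2 and MI moDC replicates 2 and 3. The channel gene Kcnn4 had a difference of log2 changes of -3.39 ± 0.39 (SE, adjusted p = 9.13e-06), with 122 ± 6.49 against 56.4 ± 20.0 CPM in moDCs and 41.2 ± 7.68 against 1.81 ± 1.25 in macrophages. Timd4, an efferocytosis receptor gene, differed by 2.51 (adjusted p = 0.00783), with 20.5 ± 7.09 against 19.6 ± 6.67 CPM in moDCs and 12.95 ± 4.68 against 70.9 ± 12.2 in macrophages. Adamdec1 (6.35, adjusted p = 0.0101), St3gal5 (1.90, adjusted p = 0.00148) and Chn2 (1.504, adjusted p = 0.0168) were higher but not against SS numbers 2 and 3 (0.103, 0.0564 and 0.188), and Fcrl1 (-3.52, adjusted p = 0.00975) was lower but not against 1 and 4 (0.464).

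Between cDC2 and moDCs 118 genes differed (54 higher and 64 lower in cDC2, 83 against either SS pair). Without MI cDC2 replicate 2 the count was 58, without SS moDC replicate 2 it was 76 and without SS moDC replicate 3 225. Trp53i11 (difference of log2 changes 2.94 ± 0.35, SE, adjusted p = 7.06e-06), Ggt5 (2.92, adjusted p = 0.00474) and Enpp1 (2.74, adjusted p = 0.00434) were higher, of which Enpp1 stood at 106 ± 8.84 against 6.97 ± 3.58 CPM in cDC2 and 53.3 ± 9.67 against 23.7 ± 9.11 in moDCs. The lysozyme gene Lyz1 (-2.60, adjusted p = 4.73e-04) and the matrix gene Ecm1 (-2.57, adjusted p = 0.00113) were lower. Cep170b (3.49, adjusted p = 0.00243) did not pass against SS numbers 2 and 3 (0.0942), C4b (-3.17, adjusted p = 0.0137) without any one of MI cDC2 replicates 2 (0.0841) and 3 (0.0522), and Trpm2 (-2.65, adjusted p = 0.0137) without any one of MI cDC2 replicates 1 (0.0816) and 3 (0.0879). Without MI cDC2 replicate 1 the difference of C4b came to -3.76 and without MI cDC2 replicate 2 the difference of Trpm2 came to -4.15.

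Between cDC1 and cDC2 549 genes differed (209 higher and 340 lower in cDC1, 399 and 576 against the SS pairs). The cDC1 receptor gene Clec9a differed by 4.70 ± 0.79 (SE, adjusted p = 4.20e-04), with 196 ± 9.48 against 188 ± 12.7 CPM in cDC1 and 0.389 ± 0.385 against 9.89 ± 0.919 in cDC2, and Ak8 by 4.07 (adjusted p = 0.00557). Bcam (adjusted p = 1.72e-05), Gab1 (adjusted p = 3.36e-05) and Jam2 (adjusted p = 0.00762) fell further in cDC1, where fitted differences are no bounds because libraries stood at 0. Bcam stood at 0 ± 0 against 29.5 ± 23.7 CPM in cDC1 and 4.18 ± 0.468 against 15.0 ± 5.12 in cDC2. Calls that ended without a single library included Mag without MI cDC1 replicate 1 (0.9999), Retnla without MI cDC1 replicate 3 (0.791), Ptprb without MI cDC2 replicate 3 (0.99999), Abcb4 without SS cDC1 replicate 3 (0.324), and Nrg2 without any one of MI cDC2 replicates 1 (0.114) and 3 (0.102) and MI cDC1 replicate 2 (0.0531). Over all 4 cell types, the MI effect of 887 genes differed by the F test (583 and 920 against the SS pairs). Without MI cDC2 replicate 3 the difference of Clec9a came to 5.66.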

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

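The counts over other splits of the libraries were planned, while the tests behind the 3 weighed patterns (heat shock, transcripts of other cells, and monocyte genes in cDC2) were chosen after those results were seen.

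For each comparison of groups, only the real split of 35 had so many changed genes, the smallest share 35 splits allow. For MI against SS the real counts and the highest of the other splits were 963 and 4 (macrophages), 631 and 3 (moDCs), 1158 and 79 (cDC1) and 1440 and 784 (cDC2). For the cell types in SS they were 1682 and 483, 2008 and 270, and 3675 and 180, and in MI 1411 and 1, 1323 and 313, and 3494 and 1988. The splits with 784 and 1988 genes displaced 1 library each. The split with 483 genes set libraries numbered 1 and 4 apart from 2 and 3, the groups of unequal no-feature share, and of the 8 splits that part all 4 pairs of moDC and macrophage libraries the highest other had 50. For differences of MI effects 4 of 100 splits were as large, the real one included (38 and highest other 338, 118 and 337, 549 and 957). In each case the 3 others kept or exchanged the state labels of 1 of the cell types (cDC2 in 2 splits but for 1 SS library), so they keep most of that cell type's MI effect and point to a structure of the samples. For the 4 cell types together 1 of 100 splits was as large (887 and 672). For the gene list tests 1 of 100 splits was as large (36 calls and 31, median of the others 15), so the preset correlation also called many lists in other splits.

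Heat shock genes fell in the MI libraries of all 4 cell types, 6 of 6 members in each. Dissociation stress raising immediate early and heat shock genes equally would lower both. The lowest immediate early median, -0.20 in moDCs (95% interval -0.57 to -0.077), argues against that. A weaker joint fall in moDCs stays open, and Jund fell in all 4. A handling difference between all SS and all MI preparations cannot be told apart from MI, because preparation and state coincide, and 0 of the 6 genes differed in MI effect among the cell types. Within SS, 4 of the 6 (Hspa1a, Hspa1b, Dnajb1 and Hsph1) stood lowest in replicate 3 of every cell type (Dnajb1 at 626, 509, 786 and 821 CPM), and why was not tested. A heat shock response in SS hearts, or its absence after MI, was not tested.

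Mural, endothelial and cardiomyocyte transcripts stood higher in SS than in MI libraries of moDCs and cDC1, and by their means in cDC2, where mural and endothelial sums of SS and MI libraries overlapped. One background RNA of fixed makeup would keep their proportions. SS ratios of cardiomyocyte to mural CPM (geometric means 14.2 in macrophages, 1.49 in moDCs, 0.340 in cDC1 and 0.879 in cDC2) were 41.7-fold apart. Macrophages, with little mural change, set this, so elsewhere it decides nothing. Of 17 tested mural and endothelial genes 94.1% were at least 2-fold lower in MI cDC1, so SS cDC1 held these transcripts. Whether mural or endothelial cells or their RNA brought them, or infarcted hearts held fewer such cells, stays open. The sorting gates are not given in the sources used here.

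Monocyte and macrophage genes were lower in MI than in SS cDC2 libraries. A smaller share of moDC-type cells at unchanged SS expression would have each gene imply the same share of moDC RNA lost. Of 26 fallen genes, 46.2% (12) left out the median share of 16.99% (3.47% to 109%) by more than 2 SE. For macrophage-type cells it was 62.5% of 24 genes (15), around a median of 6.82% (0.279% to 105%). Both values argue against one such cell type as the whole source. Mixtures of several cell types, classical monocytes, and an effect of MI on cDC2 themselves may each contribute and were not tested.

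Single libraries stood apart from the other 3 of their group in 58 of 600 groups (9.67%). In 496 groups of gene values 46 did, some because the other 3 had 0 reads. Replicate 1 of MI cDC1 had 7, and replicate 2 of MI macrophages and replicate 3 of SS cDC2 had 6 each. Values are CPM unless named otherwise. MI cDC1 replicate 1 was high in Gbp4 21.1, H2-DMa 1049, Mag 0.926, Mmp14 45.2 and Malat1 percent of reads 0.486 and low in Ero1l 52.8 and P4ha1 43.2. MI cDC1 replicate 2 was high in Adm 0.592 and fibroblast sum 841. MI cDC1 replicate 3 was high in Retnla 3.34. MI cDC1 replicate 4 was high in cardiomyocyte sum 25.2. MI macrophage replicate 1 was high in NK and ILC sum 14.8 and low in Cd36 52.6. MI macrophage replicate 2 was high in Adam8 149, Arg1 307, Fn1 1363, Ms4a4c 179, Saa3 111 and mural sum 37.7. MI macrophage replicate 3 was high in Tlr11 2.48. MI moDC replicate 2 was high in Jchain 0.495 and S100a9 0.396. MI moDC replicate 3 was high in Notch3 0.0997 and Steap4 0.997. MI moDC replicate 4 was high in Tinagl1 0.7004 and mast cell and basophil sum 0.1001. SS cDC1 replicate 1 was high in H2-DMa 1426 and reads in genes 16531349 and low in genes detected 11747. SS cDC1 replicate 2 was high in Gab1 5.88, Spon1 1.14 and neutrophil sum 9.10. SS cDC1 replicate 3 was high in Abcb4 1.59, Sirpb1a 0.0992 and Tap1 646. SS cDC2 replicate 1 was high in Naalad2 0.294. SS cDC2 replicate 2 was high in C4b 39.6 and Dkk3 0.745. SS cDC2 replicate 3 was high in Ccl8 3.83, Homer2 0.109, Kit 63.0 and erythroid sum 3.28 and low in Ffar2 0.328 and Hmox1 141. SS cDC2 replicate 4 was high in Cdh1 44.2, Cldn1 49.9 and Cyp8b1 0.187. SS macrophage replicate 1 was high in Ccl17 0.0953. SS macrophage replicate 3 was high in Saa3 6.16. SS macrophage replicate 4 was high in Fn1 176, Upb1 0.583 and neutrophil sum 198. SS moDC replicate 2 was high in Stard4 26.7 and Tagln 71.6. SS moDC replicate 3 was high in Spib 78.2, Upb1 36.9 and plasmacytoid dendritic cell sum 411. SS moDC replicate 4 was high in Spon1 12.1.

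The MI effect differed among the 4 cell types for 85 of 164 named genes, 84 of which follow with the adjusted p of edgeR's F test after each name. Genes named in macrophages were Kcnn4 8.16e-09, Ccr2 1.78e-08, Timd4 9.63e-07, Ndrg1 2.40e-06, Adam8 4.47e-06, H2-Ob 6.10e-06, Itgax 6.66e-06, Naaa 2.36e-05, Hepacam2 3.19e-05, Cd36 4.35e-05, Cd86 5.56e-05 and Itgam 6.35e-05. They also were Zbp1 1.59e-04, Tspan8 2.29e-04, Ctsd 3.84e-04, Osm 3.84e-04, Vegfa 0.00106, Haao 0.00121, Cd207 0.00124, Tlr11 0.00183, Lgals3 0.00247, Ero1l 0.00332, Fn1 0.00494 and Ikbke 0.00669, and Fcgr4 0.00754, Mmp14 0.00823, Batf3 0.00838, Abcg1 0.0105, Arhgap24 0.0129, Ccrl2 0.0161, Ccl3 0.0280, Cox5a 0.0282, Ms4a4c 0.0318 and Rsad2 0.0492. Further genes named in moDCs were Gas6 3.25e-07, Tgfbi 8.38e-06, Zbtb18 2.18e-05, Clec9a 4.25e-04, F13a1 5.25e-04, Acta2 0.00177, Fxyd7 0.00586, Icosl 0.00777, Oasl1 0.00806, Insig1 0.0101, Ebi3 0.0159, Tinagl1 0.0189, Gbp4 0.0288 and Steap4 0.0347. Those in cDC1 were Mfge8 4.16e-08, Lpar1 1.50e-06, Tnf 2.88e-06, Lyz2 5.61e-06, Nfkbia 7.33e-06, Tnfsf9 1.06e-05, Nfkbiz 1.52e-05, Bcam 3.47e-05, Adgre1 3.94e-05, Axl 4.35e-05, Wfdc17 6.37e-05 and Emb 7.32e-05, and Flot1 1.75e-04, Hmox1 1.97e-04, Gbp2 0.00196, Cd209a 0.00228, Dok3 0.00274, Plau 0.00345, Sorbs2 0.00925, Jam2 0.0178, Ier3 0.0242, Rgs4 0.0301 and Lgmn 0.0452. In cDC2 they were Pparg 4.64e-06, Ecm1 3.28e-05, Enpp1 7.64e-05, Il1rn 1.85e-04, Thbs1 0.00169, Tnfrsf9 0.00704, Cxcl10 0.00882, Ciita 0.0151, Slc16a14 0.0187, Fabp4 0.0235, Cycs 0.0276, Ly6c2 0.0338 and Il18 0.0345. Between moDCs and macrophages the MI effect also differed for Adamdec1 0.0101, Ctnnd2 0.0217, St3gal5 0.00148, Chn2 0.0168, Myl9 0.0496, Tagln 0.0457 and Fcrl1 0.00975. The Ctnnd2, Myl9 and Tagln calls ended without several single libraries (adjusted p 0.0520 to 0.121). Between cDC2 and moDCs it differed for Cep170b 0.00243, Trp53i11 7.06e-06, Ggt5 0.00474, Tbc1d16 0.0420, C4b 0.0137, Trpm2 0.0137, Lyz1 4.73e-04 and Slc27a3 0.0462, of which Tbc1d16 and Slc27a3 ended without most single libraries (0.0505 to 0.160). Between cDC1 and cDC2 it differed for Mag 0.00758, Retnla 0.0133, Nrg2 0.0283, Ak8 0.00557, Ptprb 0.0433, Gab1 3.36e-05 and Abcb4 0.00510, and Ptprb ended without most single libraries (0.0552 to 0.99999).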

How the results depend on the processing

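The replicate left out, RLE and upper-quartile factors, both filters, DESeq2, limma-voom, the replicate block and only the samples compared were planned. The SS pairs alone, the 3 deep libraries left out and both covariates were added after the data were seen. The cause was not tested for the changed counts below, except that fewer samples enter the SS pairs.

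Counts of changed genes not printed here stayed within 1.5 times of those reported. With limma-voom the counts were 1491 in macrophages, 1016 in moDCs, 2490 for moDCs against macrophages in MI, 2432 for cDC2 against moDCs in MI, 293 for the difference between cDC2 and moDCs, 849 for that between cDC1 and cDC2, and 1380 for the 4 cell types together. With DESeq2 the differences between moDCs and macrophages and between cDC2 and moDCs came to 118 and 233. Fitting only the samples compared gave 1202 for cDC2 against moDCs in SS and 2188 in MI. It also gave 1134 for moDCs against macrophages in SS, 56.0% of them higher against 66.4%. The estimated correlation left 4 of 36 list calls, and all 4 were among the 36.

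With the mural and endothelial covariate 124 genes changed in moDCs and 34 in cDC1, in both of which it parts SS from MI. The counts were 983 and 1139 for moDCs against macrophages and cDC2 against moDCs in SS, 167 for the difference between cDC1 and cDC2, and 525 for the 4 cell types together. With this covariate the log2 changes of 4 cDC1 genes reversed: B2m to 0.19, Ly6c1 to 0.27, Ero1l to -0.00161 and Esam to 0.86. With SS numbers 1 and 4 only, the counts were 728 and 1182 for these SS comparisons, 24 for the difference between moDCs and macrophages and 583 for the 4 cell types together, and with numbers 2 and 3 only 1053 and 896.

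Same-numbered libraries of the other pairs were not treated as pairs, since their correlations reached down to -0.0578 and not all were over 0.1. With a replicate block the difference between cDC2 and moDCs came to 189 genes, and other counts moved by less than 1.5 times. Leaving out 1 replicate gave 407 to 741 genes in moDCs, 882 (without MI replicate 1) to 1550 in cDC2, and 792 (without MI cDC2 replicate 2) to 1174 for cDC2 against moDCs in MI. For the difference between moDCs and macrophages it gave 21 (without MI moDC replicate 1) to 55, and for that between cDC2 and moDCs 58 (without MI cDC2 replicate 2) to 225 (without SS moDC replicate 3). Other ranges were 675 to 869 in macrophages, 810 to 1124 in cDC1, 379 to 555 for cDC1 against cDC2 effects and 31 to 39 list calls.

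Of 58 macrophage, 52 moDC, 57 cDC1 and 66 cDC2 genes named for MI against SS, 6, 11, 6 and 6 lost their call under any planned setting other than a replicate left out, and 5, 15, 9 and 17 under a replicate left out. Under the added settings 12, 35, 49 and 14 did, in cDC1 mostly with the mural and endothelial covariate. Per library 3 counts equal 0.1803 to 0.328 CPM, and levels under a library's own value rest on 1 or 2 reads.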

Other observations

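The test of the hypothesis in this part was chosen after the lists were seen. Of 24 maturation genes 7 fell and 17 did not pass in cDC1 (median log2 change -0.93, list adjusted p = 0.348 with estimated correlation), where the Ebi3, Icosl and Cd80 calls ended with the mural and endothelial covariate, and 2 rose in cDC2 (0.43). A candidate explanation is an opposite MI effect on this programme in the 2 cell types. The difference of the MI effects, cDC1 minus cDC2, had a median of -1.003, with Icosl, Tnfrsf9, Ccl5, Ebi3 and Cd86 lower, 0 of 24 higher and 19 not passing. Camera with an estimated correlation gave p = 0.0740 (8.34e-08 with the preset correlation), so beyond these 5 genes a list-wide difference stays open.

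Among genes that changed in all 4 cell types, chosen after their values were seen, Cd207 (log2 changes -4.95 in macrophages, -4.27 in moDCs, -1.91 in cDC1 and -3.42 in cDC2) and Il1a (-1.52, -2.004, -1.44 and -2.31) fell and Jak3 (1.46, 1.07, 1.44 and 1.52) rose. None passed in cDC1 with the mural and endothelial covariate, which nearly follows state there.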
